A study of Mus musculus with 92 samples.

How the data were processed

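Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to locate the cohesin subunits STAG1, STAG2 and STAG3 and the insulator protein CTCF in mouse cells. The values used here are 30 peak lists deposited by the authors, each holding the intervals in which a peak caller found more reads than in the background. The series holds 92 samples, and those without a peak list were not analysed here. They include other antibodies, input libraries, and STAG antibodies in mutant cells, among them STAG3 in STAG3-knockout GSC. Wild-type STAG1 and STAG2 lists came from 5 cell types: embryonic stem cells (ESC), epiblast-like cells (EpiLC), primordial germ cell-like cells of the stages named d2PGCLC and d4c7PGCLC in the labels, and germline stem cells (GSC). STAG3 lists came from wild-type GSC, and CTCF lists from GSC of 4 mutant genotypes.

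Per the submitters' processing notes, Trim Galore 0.4.1, cutadapt 1.9.1, Bowtie2 2.3.4.1, SAMtools 1.7, bedtools 2.29.2, deepTools 3.5.0 and MACS2 were used, with the builds mm10 and GRCm38.p3. The role and the options of each tool, the version of MACS2 and the control library behind each list are not given in the sources used here. The columns follow the MACS2 narrowPeak layout. The authors' lists give for each peak its fold enrichment at the summit over the local background, a linear ratio. The deposited lists also give −log10 of a p-value and −log10 of a q-value per peak, and a score, 10 times −log10 q as a whole number. A peak's fold enrichment and score are the authors' values for that peak, and were used only to rank or filter peaks within a list. A few values of fold enrichment are printed as a description. Every deposited list held only peaks with −log10 q of at least 2.

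The 26 STAG lists were called per library. Each CTCF list was called on pooled replicates, per the peak names and the labels, so that each genotype had 1 list and no replicate error could be given for CTCF. Peak names of the STAG3 lists name another working directory than those of the STAG1 and STAG2 lists, so a separate calling run for STAG3 cannot be told apart from the antibody. The labels do not say whether replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. GSC came from another cell line (AAG, carrying Acrosin-EGFP and beta-Actin-EGFP) than the other cell types (BVSC, carrying Blimp1-mVenus and Stella-ECFP). Cell type and line therefore cannot be separated for GSC. PGCLC had been sorted for the Blimp1-mVenus signal and GSC for the AAG signal, per the labels' protocols.

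The sequencing depth behind a list is not part of it and is unknown here, so no interval or detection limit that needs depth was computed. A deeper library can give a longer list, and a place without a peak is a place where none was called, not a place without protein.

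Peaks on chromosomes 1 to 19, X and Y were used, which were all peaks of all lists. Peaks were counted as overlapping when they shared at least 1 bp. A site of a group was an interval covered by at least 2 of its lists. Shared GSC CTCF sites were merged CTCF intervals called in all 4 genotypes. Since CTCF was read only in GSC mutants, the CTCF share of another cell type is measured against sites of another cell type, line and genotype. The similarity of 2 lists was the Jaccard index, the base pairs they share divided by the base pairs in their union. Overlaps between site sets were set beside the mean of 100 shuffles of positions within each chromosome with a fixed seed.

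Genes came from a RefSeq table of GRCm38.p6 with 21887 protein-coding genes. The design called for promoter windows, but the table gives no strand, so the start of a gene could not be told from its end. A window of 2500 bp to each side of either gene end was used instead, a choice made after seeing the data, and is called here the gene end. Such windows covered 6.84% of the chromosomal span. Gene bodies covered 38.8% of it. The windows mix promoters with 3′ ends. Genes that share an end, as many clustered protocadherins do, can be counted through the same site.

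The 17 gene lists were fixed before the data were examined, as were the rule for named genes and, except where stated, the comparisons and tests. Their names and sizes were naive pluripotency (16 genes), core pluripotency (10), formative pluripotency (14), early PGC (12), late germline (17), spermatogonial (20), meiotic (21), cohesin and CTCF (20), imprinted (18), Hox (39), clustered protocadherin (57), ribosomal protein (77), fibroblast feeder (12), Sertoli (10), mesendoderm (10), neural (12) and olfactory receptor (1106). Fibroblast feeder and Sertoli genes mark other cell types that a GSC culture could hold. In all, 1471 list genes were matched by symbol, 1 of them through a synonym, and 3 that are not protein-coding were not tested.

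Named genes followed 3 rules: the cohesin genes Stag1, Stag2, Stag3 and Rad21 with Ctcf; list genes with a gene-end peak in every list of a group and in no list of the other, up to 10 per direction by fold enrichment in the first list; and the protein-coding genes nearest to the 5 sites with the highest fold enrichment in the first list among those called in every list of a group and in no list of the other. The text names a selection of these. Any other gene or region is named with the words that it was chosen after its values were seen.

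Peak numbers (on the log2 scale), gene-end shares and CTCF shares of STAG1 and STAG2 were compared by two-sided exact permutation of the antibody within each cell type, over 36000 arrangements. Cell type similarity was tested by one-sided permutation: exactly, over all 945 pairings of the 10 STAG1 lists, and with 100000 resamples for the 13 STAG2 lists. GSC lists were compared with lists of the other cell types by two-sided exact permutation within each antibody, over 12870 arrangements. STAG3 lists were compared with STAG1 and STAG2 lists of GSC by two-sided exact permutation, where the smallest p the design allows is 0.1. Gene lists were tested with two-sided Fisher's exact tests against all other protein-coding genes, with Benjamini-Hochberg adjustment over all 187 tests. Gene lists were also compared between STAG3 and STAG2 with exact McNemar tests, adjusted over the 17 lists. The threshold was 0.05. Genes of a family are not independent of each other, so these p-values describe counts of genes. Differences of the STAG2 against STAG1 effect between cell types were tested by exact permutation, adjusted over 30 tests. These tests, the classes of STAG3 sites by overlap, and the share of CTCF sites that carried each protein were not part of the plan and were chosen after seeing the data.

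The alternatives were a −log10 q of at least 5, an overlap of at least 50% of the shorter interval, sites called in any or in every list of a group, lists of equal length (each list reduced to its peaks with the highest fold enrichment), all contigs, a window of 1000 bp, leaving out each of 26 lists in turn, and a replicate block (lists paired by replicate number). A CTCF site called in any genotype was added after seeing the data.

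Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and Matplotlib 3.10.9 was used. The overlap and permutation code was checked against bedtools 2.31.1 and SciPy, and 80 of 80 comparisons gave the reference value. The gene list test was tested on simulated data in 50 simulations of the GSC STAG2 sites over 21887 genes. There, 150 of 150 planted lists, in which 90% of genes had a site against 25.3% of other genes, and 5 of 9200 other tests passed the threshold. Sites were drawn for each gene independently, so the simulation does not cover lists whose genes share sites. Weaker differences were not planted.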

Results

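Cohesin is a ring-shaped protein complex that folds chromosomes into loops and holds sister chromatids together. Each complex carries a STAG subunit. STAG1 and STAG2 are found in most dividing cells, and STAG3 is best known from meiosis. The study asked where STAG3-cohesin sits in mitotic cells of the mouse male germline, and how its places relate to those of STAG1, STAG2 and the insulator protein CTCF, at which cohesin often stops. The peak lists analysed here cover a series of cell states in culture. ESC are pluripotent stem cells, EpiLC resemble the epiblast, d2PGCLC and d4c7PGCLC resemble early germ cells, and GSC are self-renewing spermatogonial cells. STAG1 had 2 lists in each cell type. STAG2 had 2 lists in ESC and EpiLC and 3 in d2PGCLC, d4c7PGCLC and GSC, and STAG3 had 3 lists in GSC. CTCF had 1 list for each of 4 GSC genotypes, so its values have no replicates. These genotypes lacked STAG3 alone, STAG2 and STAG3 (here STAG1-only cells), STAG1 and STAG3 (STAG2-only cells), or STAG1 and STAG2 (STAG3-only cells). Median peak widths lay between 271 and 408 bp, and the depth behind each list is unknown.

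STAG2 had more peaks than STAG1 in ESC, EpiLC, d2PGCLC and GSC. In ESC, the STAG2 lists held 72729 and 73195 peaks and the STAG1 lists 39055 and 29222. EpiLC had the widest gap, with 83949 ± 1351 STAG2 peaks and 20238 ± 7804 STAG1 peaks (SD, n = 2 each), a ratio of geometric means of 4.31. The ratio was 2.16 in ESC and 2.03 in GSC, and d2PGCLC had 56598 ± 15628 STAG2 peaks (SD, n = 3) and 24129 ± 3806 STAG1 peaks (SD, n = 2). In d4c7PGCLC the numbers were alike, with 42341 ± 10112 STAG2 peaks (SD, n = 3) and 40252 ± 2490 STAG1 peaks (SD, n = 2), a ratio of 1.03. GSC had the fewest peaks of both proteins, with 10778 or fewer in each STAG1 list and 25979 or fewer in each STAG2 list. Over the 5 cell types, the mean difference was 1.10 on the log2 scale (two-sided exact permutation p = 0.000306). Because a deeper library can give a longer list, this is a difference between the authors' calls.

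**Figure D1:**
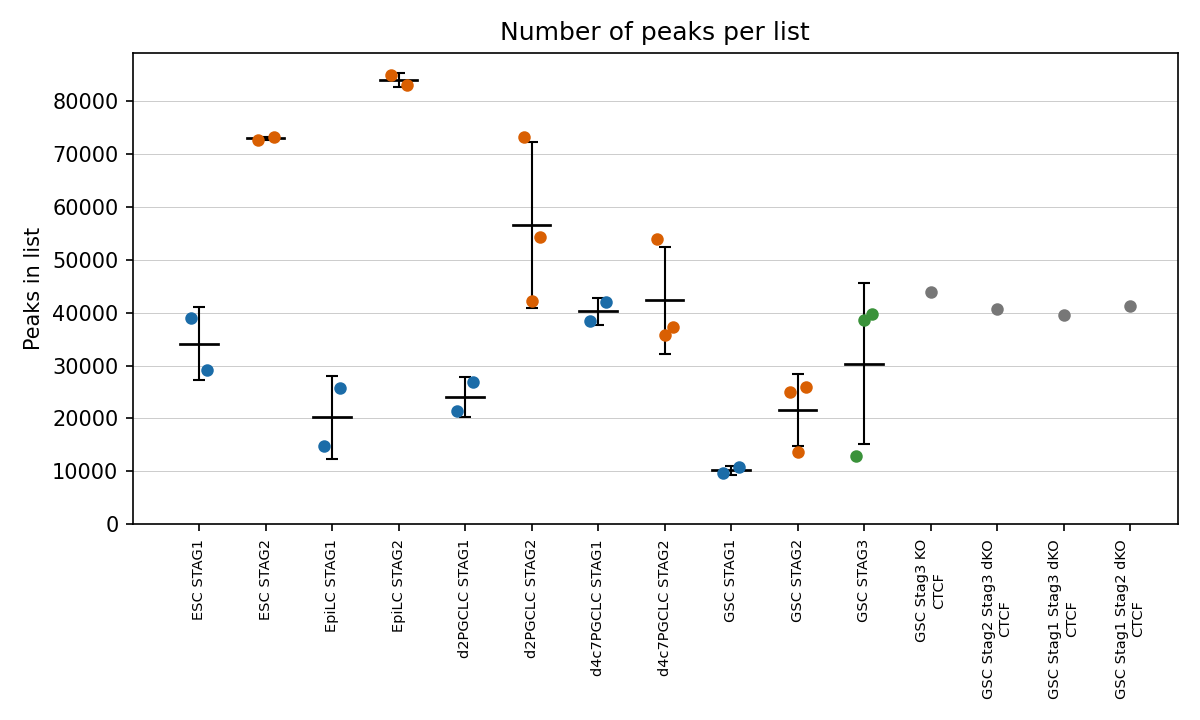
Number of peaks in each of the 30 lists, by cell type, protein and, for CTCF, genotype (dKO, double knockout). Each point is a list, and bars give the mean and SD of groups with replicates. The EpiLC STAG2 lists, at 82994 and 84904 peaks, sit above all others, and the GSC STAG1 lists, at 9641 and 10778, are the shortest.

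STAG1 peaks lay mostly at CTCF sites, whereas STAG2 had many peaks elsewhere and more of them near gene ends. At the sites called for CTCF in all 4 GSC genotypes lay 75.6% ± 6.24 of STAG1 peaks in ESC, 84.5% ± 9.16 in EpiLC, 78.8% ± 4.25 in d2PGCLC, 70.7% ± 2.13 in d4c7PGCLC and 98.0% ± 1.29 in GSC (SD, n = 2 each). For STAG2 the shares were 41.4% ± 0.413 in ESC and 38.3% ± 0.499 in EpiLC (SD, n = 2 each), and 47.3% ± 8.24 in d2PGCLC, 59.2% ± 7.11 in d4c7PGCLC and 70.2% ± 13.1 in GSC (SD, n = 3 each). The mean difference, STAG2 minus STAG1, was −30.2 percentage points (two-sided exact permutation p = 2.78e-05). The smallest gap, −11.5 points, was in d4c7PGCLC. Gene ends held 28.3% ± 4.86 of STAG2 peaks in GSC (SD, n = 3), against 18.5% ± 0.173 of STAG1 peaks (SD, n = 2). STAG2 minus STAG1 was 9.82 points in GSC, 6.90 in d4c7PGCLC, 4.40 in d2PGCLC, 4.24 in EpiLC and 3.19 in ESC. The mean difference over the 5 cell types was 5.71 points (two-sided exact permutation p = 2.78e-05). When all lists were reduced to the same number of their peaks with the highest fold enrichment, the CTCF difference shrank to −3.47 points (exact permutation p = 2.78e-05). The gene-end difference was then 0.477 points and did not pass the threshold (exact permutation p = 0.0901).

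**Figure D2:**
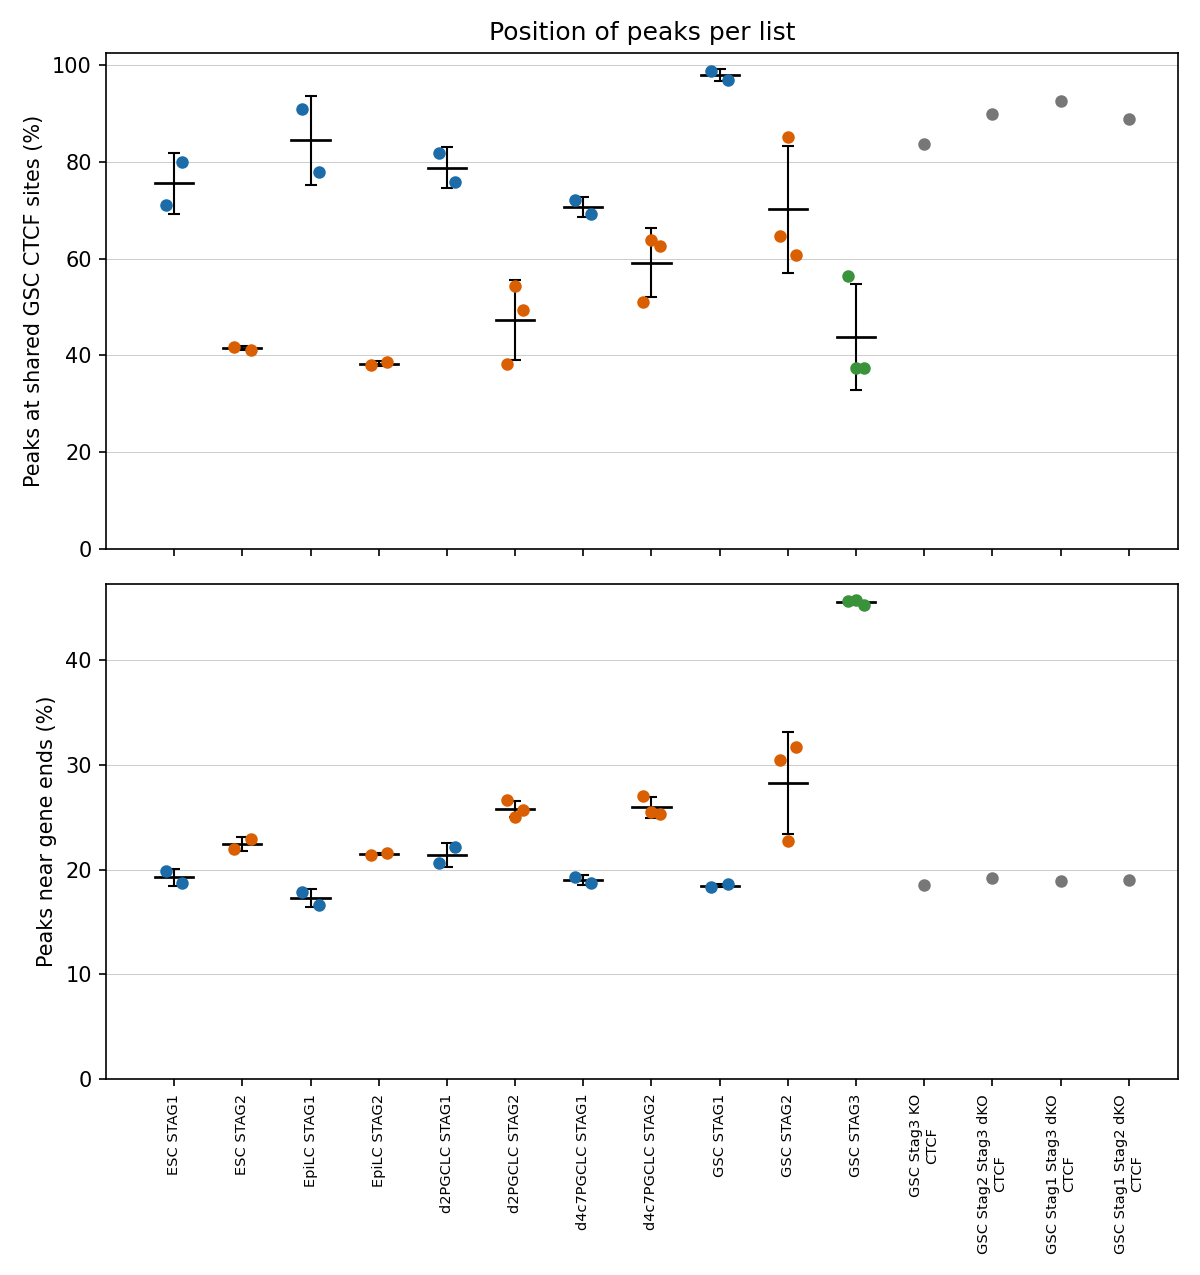
Percent of the peaks of each list that lay at CTCF sites shared by the 4 GSC genotypes (top) and within 2500 bp of a gene end (bottom), by cell type and protein. Each point is a list, and bars give the mean and SD. The GSC STAG3 lists sit at 45.2% to 45.7% near gene ends, above every STAG1, STAG2 and CTCF list. CTCF lists lie high in the top panel because the sites were defined from them.

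Most STAG1 sites were also STAG2 sites. Of the STAG1 sites, 98.5% overlapped a STAG2 site in ESC, 99.3% in EpiLC, 99.3% in d2PGCLC, 81.7% in d4c7PGCLC and 97.7% in GSC, where shuffled positions gave at most 2.64% on average. In the reverse direction, 44.8% of STAG2 sites overlapped a STAG1 site in ESC, 13722 of 72156 did in EpiLC, 37.4% in d2PGCLC, 73.9% in d4c7PGCLC and 42.4% in GSC. STAG2 sites shared with STAG1 lay at CTCF sites in 82.2% of cases in ESC and 99.9% in GSC. STAG2 sites without STAG1 did so in 19.8% of cases in ESC, 32.2% in EpiLC, 28.9% in d2PGCLC, 12.6% in d4c7PGCLC and 53.4% in GSC. d4c7PGCLC had the most STAG1 sites without STAG2, 6438, of which 58.0% lay at CTCF sites. Without STAG1 replicate 1 the EpiLC share was 33.4%. These overlaps have no test, and with lists of equal length the reverse share was 81.6% in ESC, 69.1% in EpiLC, 78.3% in d2PGCLC and 75.0% in GSC.

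Sites called for STAG2 in every list and for STAG1 in none recurred near the same genes in several cell types. They are named by the nearest protein-coding gene. Other features at these places were not looked at, and a link to the gene was not tested. Being chosen by fold enrichment, they lay far above the rest of a list. In ESC STAG2 replicate 1 the site at Ilf2 had 437, against a list median of 7.98. A site at the end of Ilf2, which encodes a subunit of a double-stranded RNA-binding complex, was among the 5 with the highest fold enrichment in ESC, d4c7PGCLC and GSC (mm10 chromosome 3, 90475574 to 90476369 in GSC). A site at the end of Prmt5, an arginine methyltransferase needed in germ cells, was among them in ESC, EpiLC, d2PGCLC and d4c7PGCLC (chromosome 14, 54517373 to 54518110 in ESC). Sites in or near Trim7, an E3 ubiquitin ligase gene, were among them in EpiLC, d2PGCLC and d4c7PGCLC, and a site at the end of Hes7, a repressor of the segmentation clock, in d4c7PGCLC and GSC. Of the sites so named, all but a GSC site in Hes7 (chromosome 11, 69124044 to 69125721) lay outside the shared CTCF sites. Among list genes, Spo11, the enzyme that makes meiotic DNA breaks, had a STAG2 peak and no STAG1 peak at an end in all lists of EpiLC and d2PGCLC. So did Pou5f1, a core pluripotency factor, in EpiLC, Zfp42, a marker of naive cells, in ESC, and Smc3, a core cohesin subunit gene, in GSC. The number of list genes of this kind was 92 in ESC, 224 in EpiLC, 63 in d2PGCLC, 7 in d4c7PGCLC and 22 in GSC. The reverse, STAG1 without STAG2, held for 8 list genes in d4c7PGCLC, among them T, a mesoderm regulator, and Ctcfl, a germline paralogue of CTCF. In ESC, EpiLC, d2PGCLC and GSC it held for 0 list genes. Among all genes the reverse held for 142 in d4c7PGCLC, 12 in ESC, 3 in EpiLC, 4 in d2PGCLC and 5 in GSC.

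On average, lists of a cell type resembled each other more than lists of other cell types, for both proteins. For STAG1 this did not hold in each cell type: the ESC lists had an index of 0.591 with each other and a mean of 0.592 with d4c7PGCLC, and the EpiLC lists 0.453 with each other and a mean of 0.456 with d2PGCLC. The mean Jaccard index of STAG1 lists was 0.597 within and 0.369 between cell types (one-sided exact permutation p = 0.00106). For STAG2 it was 0.543 within and 0.334 between (one-sided permutation p = 1e-05, the smallest the resamples can give). The index is bounded by the lengths of the lists. GSC peaks covered 3.27 megabases for STAG1 and 7.68 for STAG2 on average, against 13.8 and 32.5 in ESC, so that low values with GSC follow in part from short lists. For STAG2, the mean index of GSC with the other cell types was 0.158 to 0.275, and among the others 0.359 to 0.530. For STAG1, GSC gave 0.196 to 0.313. Of the 38097 STAG1 sites found in any cell type, 5694 (14.9%) were called in all 5, and 99.9% of these lay at CTCF sites. Of the 93058 STAG2 sites, 14063 (15.1%) were called in all 5, and 90.9% of these lay at CTCF sites, against 7.06% of the STAG2 sites called in a single cell type. d4c7PGCLC alone had 7315 STAG1 sites and EpiLC alone 15999 STAG2 sites. With lists of equal length, 29.9% of STAG2 sites were called in all 5 cell types.

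**Figure D3:**
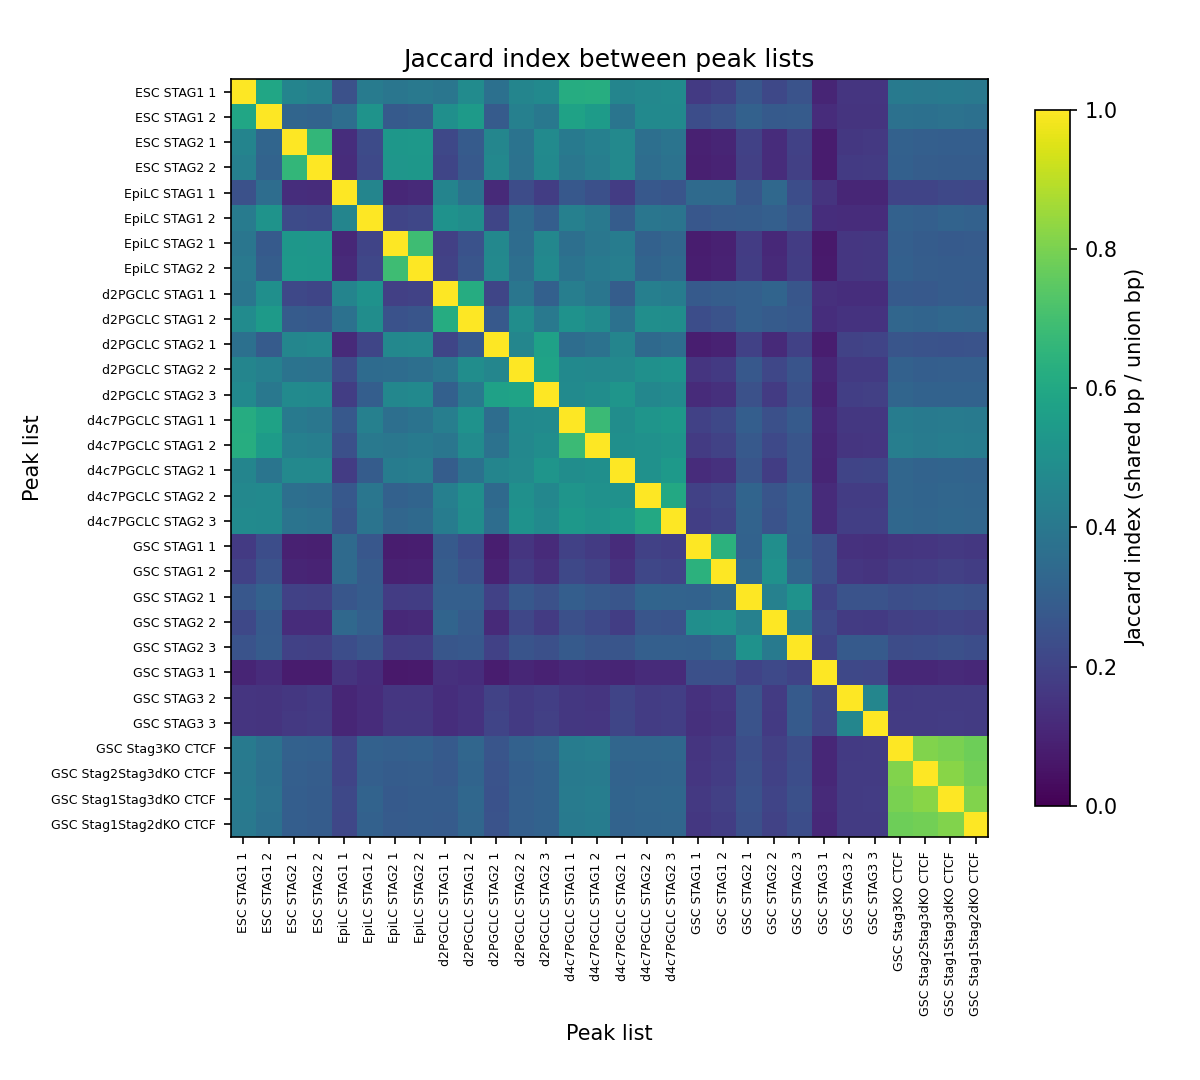
Jaccard index (base pairs shared over base pairs in the union) between all pairs of the 30 peak lists, labelled by cell type, protein and replicate. The CTCF lists form the block with the highest values, 0.779 to 0.821. STAG3 replicate 1 had 0.219 and 0.212 with the other STAG3 lists, which had 0.460 with each other.

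GSC had no call at many sites that the other cell types shared, and more of their peaks lay at the CTCF sites called in GSC. Sites called in every cell type but GSC numbered 6124 for STAG1 and 17419 for STAG2, and those called in GSC alone 128 and 2549. GSC lists were the shortest for both proteins, so many such sites can follow from fewer calls. Some genes had a STAG1 peak at an end in all lists of the other cell types and in none of GSC. They included Mycn, a growth regulator of stem cells, Stra8, the gatekeeper of meiosis, and Hoxd12 and Hoxd13, distal limb patterning genes. For STAG2 they included Pou5f1 and Rps27, a ribosomal protein gene, and for both proteins Pcdhga12, a clustered protocadherin. In all, 28 of 1471 list genes were of this kind for STAG1 and 55 for STAG2. Among all 21887 protein-coding genes it was 928 and 1040. Of the reverse kind were 0 list genes for either protein. The share of peaks at CTCF sites was 21.5 points higher in GSC than in the other cell types (two-sided exact permutation p = 0.000311). These CTCF sites were called in GSC, so only GSC were measured against sites of their own cell type. The test cannot tell this from a higher share in GSC. The share on chromosome X was 1.48% ± 0.0261 for STAG1 (SD, n = 2) and 1.37% ± 0.107 for STAG2 (SD, n = 3) in GSC. The difference from the others was −0.762 points (two-sided exact permutation p = 0.00117). Gene-end shares differed by 1.61 points and did not pass the threshold (two-sided exact permutation p = 0.192), but did without STAG2 replicate 2 of GSC, at 3.00 points (exact permutation p = 0.0266). With lists of equal length, the CTCF difference was 4.82 points (exact permutation p = 7.77e-05) and the X difference turned to 0.222 points (exact permutation p = 0.0251). These tests permute lists, while with cell types as units p cannot fall below 0.2, and GSC also differ from the rest in cell line.

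Clustered protocadherin genes, neuronal adhesion genes whose promoters are known to bind CTCF and cohesin, had sites at their ends more often than other genes in most lists of the earlier stages. In ESC, 50 of 57 had a STAG1 site and 54 of 57 a STAG2 site (Fisher's exact test, adjusted p = 4.88e-23 and 7.37e-12). The list passed in d2PGCLC, d4c7PGCLC and GSC for both proteins, and in EpiLC for STAG2. For STAG1 in EpiLC the call rested on the lists and the site rule: 11 of 57 had a site and did not pass. Without replicate 1 it was 40 of 57 and without replicate 2 it was 15 of 57, where each peak of the remaining list counted as a site. Sites called in any list gave 42 of 57 there, and the narrower window 10 of 57, and both settings passed. Hox genes, which set positional identity, passed for STAG1 in all 5 cell types, with 18 of 39 in ESC and 20 of 39 in d4c7PGCLC. For STAG2 they passed in EpiLC, d2PGCLC and GSC. Hox genes also share sites: these STAG1 counts rest on 14 distinct sites in ESC and 14 in d4c7PGCLC. Genes of cell states passed both in their own stage and in others. In their own stage these were naive pluripotency genes for STAG2 in ESC (15 of 16), formative genes for STAG2 in EpiLC (13 of 14), and early PGC genes, the list of Prdm1 and Tfap2c, for both proteins in d4c7PGCLC (9 and 10 of 12). Core pluripotency genes passed for STAG1 in ESC and d4c7PGCLC (7 of 10 each) and for STAG2 in EpiLC (10 of 10). Outside their stage, neural genes passed for STAG2 in ESC (12 of 12) and EpiLC (11 of 12), mesendoderm genes for STAG2 in d2PGCLC (10 of 10), and spermatogonial genes (17 of 20) and fibroblast feeder genes (12 of 12) for STAG2 in EpiLC. Ribosomal protein genes passed for STAG2 in EpiLC (55 of 77) and for STAG1 in d4c7PGCLC (35 of 77). Olfactory receptor genes, best known from sensory neurons of the nose, passed as lower for every protein and cell type. In all, 47 of 187 tests passed, 35 as higher and 12 as lower. With lists of equal length 13 passed as higher and 12 as lower, and with a window of 1000 bp 19 and 12, so that the loss lay among the higher calls. Every call named here for cell-state, fibroblast feeder and ribosomal protein genes ended with lists of equal length. So did those for clustered protocadherins except for STAG2 in ESC, d4c7PGCLC and GSC, while the Hox calls stayed. With the narrower window, the mesendoderm, neural and fibroblast feeder calls ended, and so did the spermatogonial and ribosomal calls outside GSC, the core pluripotency calls in all cell types including GSC, and the Hox calls except for STAG1 in GSC. With sites called in any list, the calls for core pluripotency and mesendoderm genes, and for formative and spermatogonial genes in EpiLC, ended as well. The formative call also ended with the stricter q (adjusted exact p = 0.0524), and the Hox call for STAG1 in d4c7PGCLC with an overlap of 50% (adjusted exact p = 0.0690). Some calls changed when a list was left out, which also changed the site rule. Core pluripotency genes did not pass for STAG1 without replicate 2 of ESC (adjusted exact p = 0.0661) or with either STAG1 list of d4c7PGCLC left out (0.0703 and 0.0581). In EpiLC, spermatogonial genes did not pass with either STAG2 list left out (adjusted exact p = 0.0764 and 0.0782), nor neural genes without STAG2 replicate 1 (adjusted exact p = 0.0717).

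Other lists did not pass but did under some settings, always as higher. Core pluripotency genes passed for STAG2 in d4c7PGCLC whichever of the 3 lists was left out (8 of 10 each, adjusted exact p = 0.0108, 0.0291 and 0.0240), with the stricter q and with sites called in every list. In ESC they passed for STAG2 with either list left out (10 of 10 each, adjusted exact p = 0.0280 and 0.0143), with an overlap of 50% and with sites called in any list. Fibroblast feeder genes passed for STAG2 in d4c7PGCLC whichever of the 3 lists was left out (9 of 12 each, adjusted exact p = 0.0108, 0.0467 and 0.0437), with the stricter q and with sites called in every list. They also passed for STAG1 there without replicate 1 (adjusted exact p = 0.0169) and with sites called in any list, and in d2PGCLC without STAG1 replicate 2 (adjusted exact p = 0.0205) or STAG2 replicate 3 (adjusted exact p = 0.0236). Hox genes passed for STAG2 in d4c7PGCLC without replicate 1 (21 of 39, adjusted exact p = 0.0131) or 2 (22 of 39, adjusted exact p = 0.0478), with sites called in every list and with lists of equal length, and in ESC with lists of equal length. Neural genes passed for STAG1 in EpiLC without replicate 1 (7 of 12, adjusted exact p = 0.0150) or 2 (5 of 12, adjusted exact p = 0.0477) and with sites called in any list. Early PGC and spermatogonial genes passed for STAG1 in d2PGCLC without replicate 1 (adjusted exact p = 0.0167 and 0.00783) and with sites called in any list, and early PGC genes for STAG1 in EpiLC with the narrower window. Ribosomal protein genes passed for STAG2 in ESC without replicate 1 (57 of 77, adjusted exact p = 0.0171), and with sites called in any list in ESC, d2PGCLC and d4c7PGCLC.

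STAG3 in GSC lay near gene ends far more often, and at CTCF sites less often, than STAG1 and STAG2. Gene ends held 45.5% ± 0.259 of STAG3 peaks (SD, n = 3), 28.3% ± 4.86 of STAG2 peaks (SD, n = 3) and 18.5% ± 0.173 of STAG1 peaks (SD, n = 2). CTCF sites held 43.7% ± 10.9 of STAG3 peaks. The differences were 17.3 points from STAG2 and 27.1 points from STAG1 for gene ends, and −26.5 and −54.2 points for CTCF sites. In each of these 4 comparisons all lists of STAG3 lay beyond all lists of the other protein, which gives the smallest p the design allows (two-sided exact permutation p = 0.1), so none can pass the threshold. The STAG3 lists differed among themselves: replicate 1 held 12832 peaks, the others 38631 and 39681. The lowest fold enrichment in a GSC list was 1.17 to 1.24 for STAG3, 2.14 to 3.06 for STAG2 and 2.11 to 2.58 for STAG1. A separate calling run for STAG3 cannot be told apart from the antibody. The share of STAG3 peaks on chromosome X was 0.701% ± 0.229 (SD, n = 3). In GSC it was 1.48% ± 0.0261 for STAG1 (SD, n = 2) and 1.37% ± 0.107 for STAG2 (SD, n = 3). Of protein-coding genes 4.41% lie there, and the peak share of every list, of any protein and cell type, was lower than that.

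STAG3 sites shared with both STAG1 and STAG2 lay almost all at CTCF sites, and those shared with neither lay mostly near gene ends. Many of the sites shared with STAG2 alone lay at CTCF sites, and many near gene ends. Of 27737 STAG3 sites, 7420 (26.8%) overlapped both STAG1 and STAG2 sites. Of these, 99.9% lay at CTCF sites and 19.3% near gene ends. Another 6227 (22.5%) overlapped STAG2 sites without STAG1, with 44.1% at CTCF sites and 49.7% near gene ends, and 114 overlapped STAG1 sites without STAG2. The remaining 13976 (50.4%) overlapped neither, with 17.8% at CTCF sites and 62.8% near gene ends. Sites with both lay high in the fold enrichment ranking of STAG3 replicate 3, at a median percentile of 86.9, and sites with neither at 48.5. In the other direction, 87.7% of STAG1 sites and 68.8% of STAG2 sites in GSC overlapped a STAG3 site. Shuffled positions gave 0.890% for STAG3 sites overlapping STAG1 or STAG2 sites, where 49.6% did. That share has no test and lay between 35.9% and 65.0% when a list was left out. Of the sites with neither, 54.5% overlapped a STAG1 or STAG2 site of another cell type. With lists of equal length, 36.3% of the sites with neither lay at CTCF sites and 67.1% near gene ends.

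**Figure D4:**
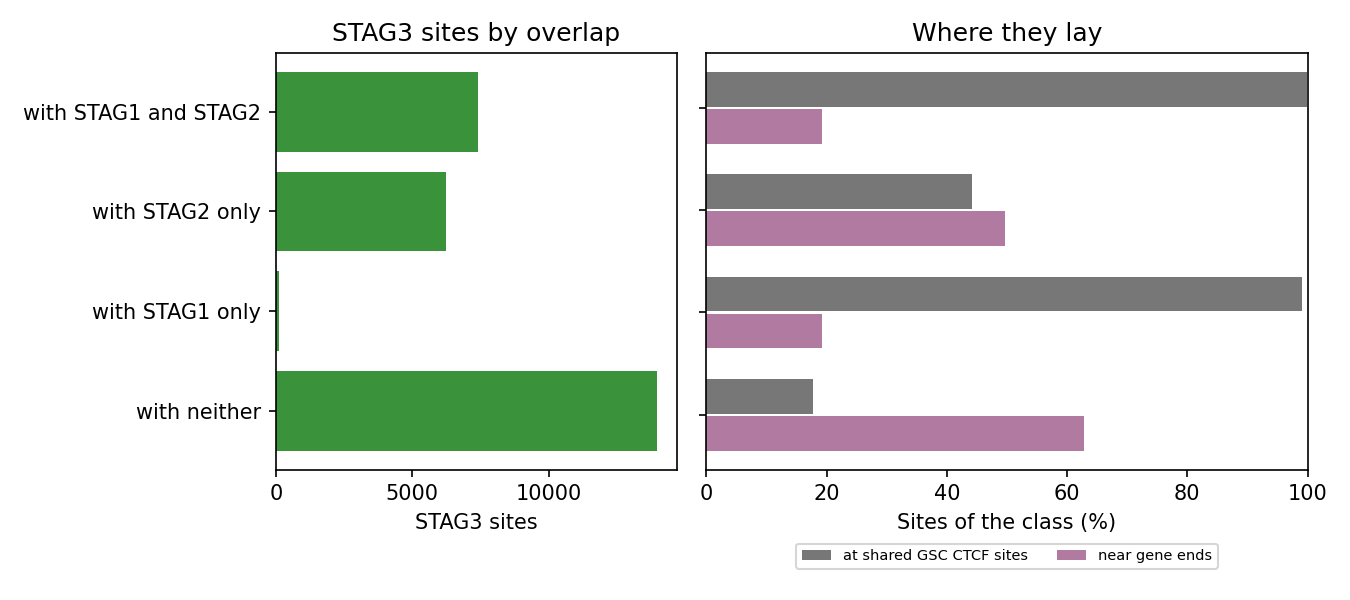
STAG3 sites in GSC by their overlap with GSC STAG1 and STAG2 sites. Bars on the left give the number of sites, and bars on the right the percent of each class at CTCF sites shared by the 4 GSC genotypes and within 2500 bp of a gene end. Sites with both other proteins lay at CTCF sites in 99.9% of cases, and sites with neither lay near gene ends in 62.8%.

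Ribosomal protein genes, which are highly expressed in all dividing cells, had STAG3 sites more often than other genes in GSC. A STAG3 site lay at an end of 69 of 77 of them (89.6%, against 55.4% of other genes; Fisher's exact test, adjusted p = 9.97e-10). In GSC the share was 19.5% for STAG2 and 6.49% for STAG1, and neither passed. Clustered protocadherins went the other way, with a STAG3 site at 13 of 57 (22.8% against 55.6%; Fisher's exact test, adjusted p = 6.26e-06). There, STAG2 lay at 31 of 57 (adjusted exact p = 3.05e-05) and STAG1 at 10 of 57 (adjusted exact p = 0.0435). The protocadherin counts rest on 13 distinct STAG3 sites, 28 STAG2 sites and 9 STAG1 sites, since these genes share ends. Olfactory receptor genes had a STAG3 site at 9 of 1106, a STAG2 site at 13 and a STAG1 site at 6, and passed as lower for all 3. Hox genes passed for STAG1 (12 of 39) and STAG2 (22 of 39), while 29 of 39 had a STAG3 site (adjusted exact p = 0.0819). These Hox counts rest on 7 distinct STAG1 sites, 16 STAG2 sites and 37 STAG3 sites. Sites called in any list gave 38 of 39 for STAG3, which passed (adjusted exact p = 2.99e-05). Spermatogonial genes, the list of Zbtb16, Gfra1 and Id4 that marks GSC themselves, passed for STAG2 with 13 of 20. So did naive pluripotency genes with 9 of 16 and core pluripotency genes with 7 of 10. These 3 calls for STAG2 ended without STAG2 replicate 1 (adjusted exact p = 0.355, 0.645 and 0.781) or replicate 3 (0.353, 0.447 and 0.780), and that for naive genes also without replicate 2 (0.115). They ended as well with lists of equal length and with sites called in every list, and the naive call with an overlap of 50% and, like the core call, with sites called in any list. The window of 1000 bp ended the core call, with 2 of 10 genes (adjusted exact p = 1), and the Hox call for STAG2 (adjusted exact p = 0.646). With lists of equal length the protocadherin call for STAG1 also ended (adjusted exact p = 0.0505). The ribosomal call ended without STAG3 replicate 2 (adjusted exact p = 0.0526) and with lists of equal length (adjusted exact p = 0.375). With sites called in any list, the protocadherin share for STAG3 was 3.63 points above that of other genes (adjusted exact p = 0.777).

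STAG3 sites lay at the ends of 16 of 20 spermatogonial, 9 of 16 naive and 6 of 10 core pluripotency genes, and did not pass there. The other lists did not pass in GSC for any of the 3 proteins, except that neural genes did for STAG3 with sites called in any list (12 of 12, adjusted exact p = 0.0441). STAG3 sites lay at 10 of 14 formative, 10 of 12 early PGC, 12 of 17 late germline, 14 of 21 meiotic, 14 of 18 imprinted, 9 of 10 mesendoderm and 10 of 12 neural genes, and at 10 of 20 genes of cohesin and CTCF. The lists that mark other cell types a GSC culture could hold had STAG3 sites at 5 of 12 fibroblast feeder and 7 of 10 Sertoli genes, against 55.5% of all genes. STAG1 sites lay at 2 of 12 and 3 of 10 of these, and STAG2 sites at 4 of 12 and 4 of 10.

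**Figure D5:**
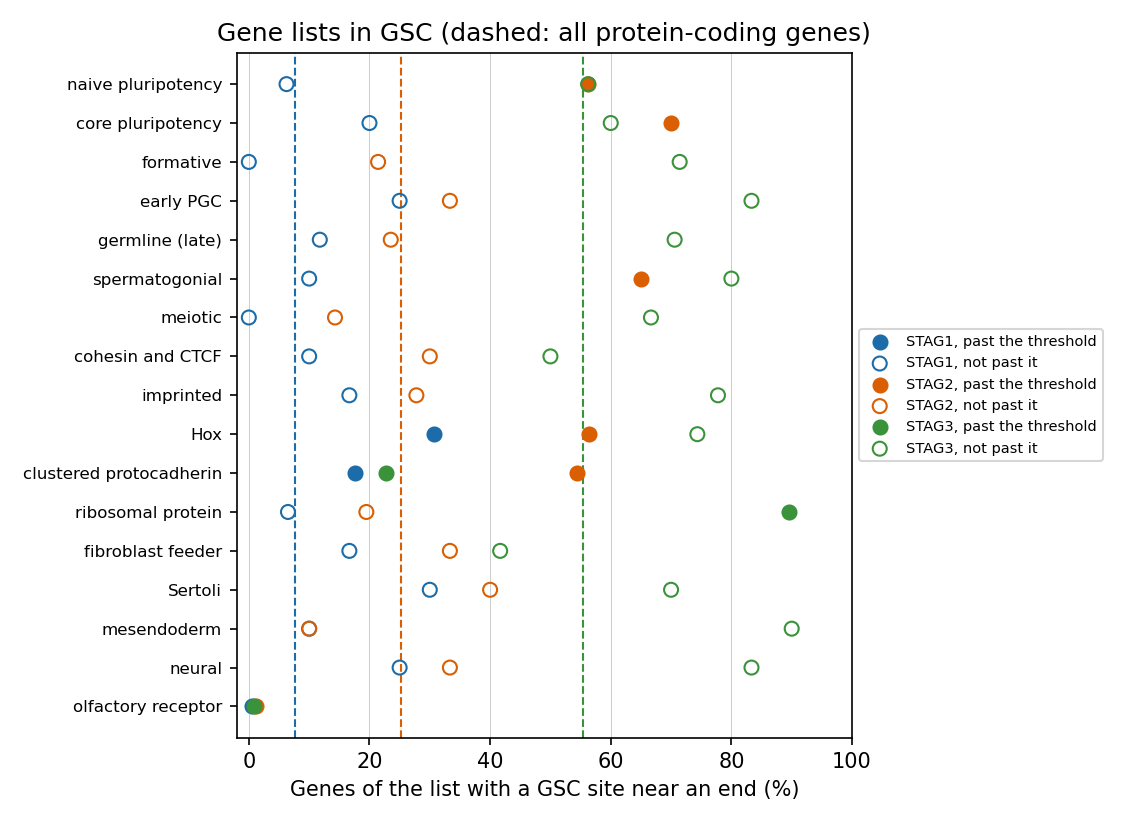
Percent of the genes of each fixed list with a STAG1, STAG2 or STAG3 site near an end in GSC. Filled circles passed the threshold in Fisher's exact test after adjustment, and dashed lines mark the percent among all protein-coding genes, 7.69% for STAG1, 25.3% for STAG2 and 55.5% for STAG3. Ribosomal protein genes sit to the right of the STAG3 line, and clustered protocadherins to its left.

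STAG3 sites lay at the ends of more genes than STAG2 sites among all genes, and among clustered protocadherins it was the reverse. Of all 21887 genes, 5057 had both a STAG3 and a STAG2 site at an end, 7085 had STAG3 without STAG2, and 477 STAG2 without STAG3. Among ribosomal protein genes, STAG3 without STAG2 held for 55 genes and the reverse for 1 (exact McNemar test, adjusted p = 2.69e-14). Meiotic genes gave 11 and 0 (adjusted exact p = 0.00553), imprinted genes 9 and 0 (adjusted exact p = 0.0166), mesendoderm genes 8 and 0 (adjusted exact p = 0.0266) and formative genes 7 and 0 (adjusted exact p = 0.0443). Among clustered protocadherins it was 1 and 19 (adjusted exact p = 0.000340). These 6 lists passed. Of the 10 splits of the STAG3 and STAG2 lists into 3 and 3, 4 gave at least as many, the real split counted. The number of lists that passed is therefore not particular to the real split. The McNemar test asks whether STAG3 exceeded STAG2 within a list, as it did among all genes. The meiotic, imprinted, mesendoderm and formative counts therefore do not set these lists apart from other genes. The count ranged from 1 without STAG3 replicate 2 and 3 without STAG3 replicate 3 to 11 without STAG2 replicate 3 and 12 without STAG2 replicate 1, and was 2 with lists of equal length.

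Genes with a STAG3 peak at an end in all 3 STAG3 lists and no peak in the 5 STAG1 and STAG2 lists of GSC numbered 1371 of 21887. Of the 1471 list genes, 1106 of them olfactory receptor genes, 23 were of this kind. These 23 included the ribosomal protein genes Rps26, Rps7, Rps23 and Rpl27a. They also included Sycp1, a building block of the synaptonemal complex, and Bhmg1 (Meiosin), the partner of Stra8 at meiotic entry. The meiotic list as a whole did not pass for STAG3. Further genes among the 23 were Dnd1, an RNA-binding protein that germ cells need to survive, the imprinted gene Dlk1, the proneural gene Neurog1 and Hoxd10. In lists of equal length each of these genes had a peak in 2 or fewer of the STAG3 lists. In the other direction there were 11 genes, and 2 of them were list genes, Pcdhb5 and Olfr1499, with a peak in all 5 STAG1 and STAG2 lists. Among sites, those with the highest fold enrichment in STAG3 replicate 1 included a site near Creb3l1 (mm10 chromosome 2, 92093521 to 92093937, between genes) and a site within Maneal (chromosome 4, 124861718 to 124862978). Another, at the end of Dnajb12, a chaperone gene, spanned 59879239 to 59880138 on chromosome 10. Sites with STAG1 and STAG2 in every list and STAG3 in none numbered 272, and 99.6% of them lay at CTCF sites, such as a site in Bst1 (chromosome 5, 43841106 to 43841704). The reverse kind numbered 2345, with 19.7% at CTCF sites and 64.0% near gene ends.

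CTCF sites were largely shared by the 4 GSC genotypes that lacked different STAG proteins. The lists held 43877 peaks without STAG3, 40732 in STAG1-only cells, 39639 in STAG2-only cells and 41282 in STAG3-only cells. Of 47107 sites in any genotype, 36623 (77.7%) were called in all 4. STAG3-knockout cells alone had 2662 sites, of which 209 lay on chromosome Y, STAG1-only cells 573, STAG2-only cells 334 and STAG3-only cells 1453. Sites missing from a single genotype numbered 238, 702, 899 and 936 in the same order. Sites called in a single double mutant ranked low in its list, at a median percentile of fold enrichment of 4.27 in STAG2-only and 5.88 in STAG3-only cells. Among list genes, a CTCF peak at the end of Lin28a, an RNA-binding pluripotency factor, was missing in STAG2-only cells, that of Hoxb13 in STAG1-only cells, and those of Stat3 and Tex15, a gene of meiotic DNA repair, in STAG3-only cells. With 1 list per genotype and no wild-type CTCF list analysed here, none of these differences could be tested.

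Of the 36623 shared CTCF sites, 39.6% carried a STAG2 site in wild-type GSC, 34.8% a STAG3 site and 23.4% a STAG1 site. All 3 proteins were called at 20.3% of them and none at 53.2%. STAG2 and STAG3 without STAG1 were called at 7.45%, STAG2 alone at 9.18% and STAG3 alone at 6.78%.

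The genes that encode these proteins had few peaks of their own in GSC. Stag3 itself had no peak in its body in any STAG1 or STAG2 list of GSC. Each STAG2 list of ESC, EpiLC and d2PGCLC had 2 or 3 peaks there, while d4c7PGCLC had 0 in its STAG1 lists and 0 or 1 in its STAG2 lists. Stag2, which lies on chromosome X, had a peak near an end in all STAG1 and STAG2 lists of GSC and in 1 of the 3 STAG3 lists. Ctcf had a peak near an end in 2 of 3 STAG2 lists, 2 of 3 STAG3 lists and 0 of 2 STAG1 lists of GSC. Stag1 had a peak near an end in 1 of the 3 STAG3 lists and in none of the other GSC lists, CTCF included. Rad21, the cleavable ring subunit, had such a peak in 1 of the 3 STAG3 lists and in none of the other GSC lists.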

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

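The tests of a difference between cell types, of peaks outside CTCF lists and of the fold enrichment of X peaks, and the use of lists of equal length to weigh an explanation, were chosen only after the result was seen.

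The STAG2 against STAG1 difference in peak number was unequal between cell types, but no test of this passed after adjustment. On the log2 scale it was 2.11 in EpiLC, 1.20 in d2PGCLC and 0.05 in d4c7PGCLC. EpiLC differed from d4c7PGCLC by 2.06 (two-sided exact permutation p = 0.0167), and d2PGCLC by 1.15 (two-sided exact permutation p = 0.0333). The same pairs stood apart in the share of peaks at CTCF sites. There, STAG2 minus STAG1 was −46.2 points in EpiLC, −31.5 in d2PGCLC and −11.5 in d4c7PGCLC, and the differences from d4c7PGCLC were −34.7 points (exact permutation p = 0.0167) and −20.0 points (exact permutation p = 0.0333). These were the 4 of 30 tests of a difference between cell types with p under 0.05, and 0 passed after adjustment (lowest adjusted exact p = 0.25). With 36 to 120 arrangements per test, none could pass by itself after this adjustment, so the result does not show that the cell types were alike.

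STAG3 peaks of GSC lay near gene ends more often than STAG1 and STAG2 peaks. List length was argued against as the whole cause, since in lists of equal length the lowest STAG3 list still lay 18.9 points above the highest STAG1 or STAG2 list. A signal that any antibody gathers at gene ends cannot be told apart from STAG3 binding: in the higher GSC STAG1 list 5.04% of gene-end peaks lay outside every CTCF list, against 25.1% to 55.9% in the STAG2 and 63.5% to 75.2% in the STAG3 lists. In lists of equal length the share was 2.04% and 1.93% for STAG1, 7.63% to 8.57% for STAG2 and 48.7% to 56.3% for STAG3, which goes against it among the strongest peaks, but a library with weaker enrichment could rank such signal higher, and enrichment cannot be compared between lists. STAG3 peaks called in cells without STAG3 would test this. The series holds such libraries of STAG3-knockout GSC, but no peak list of them was used here. A separate calling run for the STAG3 lists, and binding of STAG3 in place of STAG1 or STAG2, remain open and untested.

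Peaks on chromosome X made up a smaller share of GSC lists than of the other lists. List length is a candidate explanation, since in lists of equal length the difference turned to 0.222 points. A lower enrichment of X peaks cannot be told apart from it: X peaks ranked below the 45th percentile of fold enrichment in 9 of 23 lists, all of them STAG1 lists, and the median percentile ranged from 35.4 to 55.1. The line and cell type of GSC remain open and untested.

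A larger share of STAG1 than of STAG2 peaks lay at CTCF sites. In lists of equal length the difference shrank to −3.47 points and still passed the threshold (exact permutation p = 2.78e-05), which argues against list length as the whole cause, though it may account for most of the difference of −30.2 points. A difference between the proteins or between the antibodies remains open and untested.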

How the results depend on the processing

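The CTCF site called in any genotype and the gene end in place of the promoter were chosen after the data were seen.

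Among the values of the comparisons under 9 other settings, 102 kept their direction and side of the threshold or moved less than their spread, 1 was weaker, 20 moved and 1 turned. The all-contigs setting gave 23 of the 102 and could move nothing, as all peaks lay on the main chromosomes. For the CTCF and gene-end shares of STAG3 against STAG1 or STAG2 in GSC, no setting could give a p under the threshold. Their side of the threshold was thus fixed, and only their direction or size could change. The count of 102 therefore includes values that could not have changed, and overstates how well the results held. For sites called in every list, the STAG1 share also called for STAG2 was 97.3% in d2PGCLC, 70.3% in d4c7PGCLC and 90.9% in GSC, STAG2 sites in all 5 cell types were 11.5%, and 2 gene lists differed between STAG3 and STAG2. For sites called in any list, the STAG1 share was 96.2% in ESC, 95.3% in EpiLC and 97.6% in d2PGCLC, STAG1 sites in all 5 cell types were 16.2%, and the clustered protocadherin difference for GSC STAG3 turned to 3.63 points (adjusted exact p = 0.777). With lists of equal length the gene-end difference between STAG2 and STAG1 was 0.477 points and the X difference of GSC turned to 0.222 points. STAG3 sites shared with STAG1 or STAG2 were 63.1%, and the STAG1 share also called for STAG2 was 86.0% in ESC, 81.9% in EpiLC, 90.1% in d2PGCLC and 86.6% in GSC. Sites in all 5 cell types were 18.9% for STAG1 and 29.9% for STAG2, CTCF sites in all 4 genotypes 78.2%, gene lists past the threshold 25, and gene lists that differed between STAG3 and STAG2 2. A window of 1000 bp gave 31 gene lists past the threshold. Apart from the smaller number of peaks or the narrower window itself, the cause was not tested.

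Leaving out each of the 26 lists in turn gave 1.02 to 1.18 (log2) for the peak number of STAG2 against STAG1, 0.749 to 3.00 points for the gene-end difference of GSC, which passed without GSC STAG2 replicate 2, and −0.833 to −0.733 points for its X difference. STAG1 sites also called for STAG2 ranged from 93.7% to 99.0% in ESC, 94.4% to 99.4% in EpiLC, 96.8% to 99.2% in d2PGCLC, 70.5% to 77.6% in d4c7PGCLC and 91.2% to 97.1% in GSC. Sites in all 5 cell types ranged from 13.03% to 16.5% for STAG1 and from 11.7% to 15.3% for STAG2, and STAG3 sites shared with STAG1 or STAG2 from 35.9% to 65.0%. Gene lists past the threshold were 44 to 50, and those that differed between STAG3 and STAG2 1 to 12. The ranges for sites and gene lists also reflect the changed site rule.

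With replicate number as a replicate block, the differences were 1.08 (log2) for peak number (exact permutation p = 0.00391), 5.45 points for gene ends (exact permutation p = 0.00195) and −29.8 points for CTCF sites (exact permutation p = 0.00195). In GSC, STAG3 minus STAG1 was −51.1 and 27.2 points for CTCF sites and gene ends (exact permutation p = 0.5), and STAG3 minus STAG2 −26.5 and 17.3 points (exact permutation p = 0.25). Of 15 same-numbered pairs, 1 had a correlation over 0.1, in a range of −0.0164 to 0.111. The median was 0.0149 in these pairs and −0.0120 in the others. Such small values do not settle whether the numbers pair the lists. Depth is unknown, and how it limits these lists could not be computed.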

Other observations

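The peaks near 1600014C10Rik and on chromosome Y were looked at only after the result was seen, and the split of the lists was planned.

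In a stretch on chromosome 7 around the gene 1600014C10Rik (mm10, 38178350 to 38198533), the GSC STAG1 lists held 18 and 17 peaks, and every other list held 4 or fewer. GSC STAG1 replicate 2 held 61 peaks on chromosome Y and replicate 1 held 0. The CTCF list of STAG3-knockout GSC held 401 peaks on chromosome Y, and the other CTCF lists 194, 188 and 70.

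Of the 10 splits of the 3 STAG3 and 3 STAG2 lists of GSC into 3 and 3, 4 gave at least as many gene lists past the threshold as the real split, itself counted. The real split gave 6, and the highest other split 9. The splits are too few for a share under 0.05, so the test could not have set the real split apart. Splits that mixed STAG3 and STAG2 lists reached as many, so the count of 6 is not particular to the real split.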
